A study of Homo sapiens with 2 samples.

How the data were processed

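The series holds 2 RNA libraries of D407 cells, 1 clusterin-treated and 1 control, and 1 table of all genes. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase I, enriched on oligo(dT) beads, fragmented and copied with random hexamers. Per the submitters' processing notes, Bowtie, TopHat and Cuffdiff were used with build hg19; versions and the counting setting for strand were not given in the sources used here. The samples' groups came from their labels.

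The authors deposited 1 RPKM value per gene and library, with a log2 fold change, a p-value and a q-value per gene. The file headers do not name the unit of the 2 level columns. The unit was read from the values. For 491 of 534 small single-exon RNA genes, both levels times the gene's length gave whole numbers within 0.02 at 1 fixed total per library. The levels are therefore whole counts scaled by length and library total. They are called RPKM here and the counts are called reads, but whole numbers cannot tell single reads from read pairs. FPKM was the unit assumed before the data were examined. The deposited p-values equalled, within 2%, the Audic-Claverie p of those reads for 482 of 486 small RNA genes, so they take account of read sampling error only. The totals by which the authors divided were 38236989 reads for the control and 33177090 for clusterin. For other genes, the transcript length was searched for at which both values were whole reads and gave the deposited p; reads were recovered for 18552 of 20642 genes above 0 (89.9%). The lowest recovered total over both libraries was 6 reads. In the authors' deposited table, the 16722 genes at 0 in both libraries carry p and q of 0, which were not taken as calls, and 28 gene names that a spreadsheet had turned into dates were restored from the link in the same row.

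Of the listed genes, 23814 had symbols and 13550 Ensembl identifiers, of which 12289 were in the reference table of names. Several genes are listed both ways. Of 21013 genes listed by symbol and matched by name, 92.7% started within 2000 bp of their RefSeq position on GRCh38, against 4.92% of 4754 matched Ensembl identifiers, so the coordinates of the table mix builds. Coordinates are printed only for genes that match GRCh38, and none are converted.

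With 1 library per group, no test between the groups was made. P-values per gene were computed only to check the deposited ones, to recover reads, and to rerun the authors' call on the recovered reads under other totals; they compare the 2 libraries, and none is given for a gene or a list. The difference was log2((clusterin RPKM + 1)/(control RPKM + 1)) among genes with a mean of at least 1 RPKM, and a difference of at least 1 on that scale was counted as 2-fold. For genes with recovered reads, the ratio of RPKM has a 95% interval from the exact Clopper-Pearson interval of the clusterin share of the reads. Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. Each gene list's median was placed among 10000 random lists of the same size. These were drawn within 20 bins of mean expression from all measured genes, small RNA genes included. A percentile below 2.5 or above 97.5 was said to stand apart. Lists with fewer than 5 measured genes have values only. The 38 lists were fixed before the data were examined, as were the size rule and the naming rule; 7 lists had too few measured genes. Older symbols were matched through RefSeq synonyms.

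The text names CLU; the 10 highest and 10 lowest genes with a symbol, leaving out antibody or T cell receptor segments and small RNA symbols as the rule listed them (MIR only before a digit, so the let-7 genes MIRLET7A1 and MIRLET7A3 were kept, although they count as small RNA genes elsewhere); up to 4 members of each list that stands apart, in its direction, and up to 2 members of any other list; and the 5 highest and 5 lowest long noncoding genes. A few genes this rule takes are not reported here. Long noncoding genes were those with symbols starting LINC or holding -AS, -IT or -OT, or on the list of well-known ones. The q threshold of 0.05 was chosen here, since the authors' deposited table states none. Other pseudocounts, filters, scalings and definitions were tried, and the closing section gives their effect.

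The steps were tested on simulated data. Of 2000 simulated genes, reads were recovered for 70.6%, and 99.7% of these lay within 5% of the simulated reads. With the pseudocount, 7.07% of 99 genes simulated as 2-fold changed passed the 2-fold rule, 96.9% of 96 simulated as 4-fold changed did, and 0 of 1784 unchanged genes did. The simulation left out small RNA genes and had counting error only. These shares therefore do not hold for the small RNA genes, which were 23 of the 29 real genes past 2-fold, or for the wider real spread. Of 100 unshifted simulated lists 6 stood apart, and of 100 lists shifted by 0.15 on the log2 scale 99 did. The simulated genes were independent of each other, which members of a real list need not be. The 4 real lists that stood apart lay only -0.05, -0.05, -0.03 and 0.08 from the median of their random lists. Shifts of that size were not simulated. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.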

Results

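RNA from D407 cells, a human cell line that the labels describe as retinal pigment epithelium (RPE), was sequenced after enrichment on oligo(dT) beads. Of the 2 libraries, 1 came from cells treated with clusterin, a secreted chaperone glycoprotein, and 1 from control cells. With 1 library per group, no difference between the groups had a replicate check, and every interval of a gene's ratio or share of reads covers counting error only. The dose and duration of the treatment were not given in the sources used here. Gene levels are called RPKM here (reads scaled to the length of the transcript and to the library total). The deposited values cannot tell single reads from read pairs. Reads recovered from these values gave library totals of 38236989 reads for the control and 33177090 for clusterin, so a level of 1 RPKM in a transcript of 1 kb stood for 38.2 and 33.2 reads. The table listed 37364 genes, of which 16722 were at 0 in both libraries and 13244 had a mean of at least 1 RPKM. RPS18, a ribosomal protein gene that every cell uses, was also listed at 0, so other genes at 0 are reported only as listed at 0.

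Both libraries held high levels of simple epithelial keratins, few RPE markers and not all epithelial markers. KRT7 stood at 407 RPKM in the control and 420 in the clusterin library, KRT18 at 254 and 247, KRT8 at 226 and 231, and KRT19 at 97.0 and 106. Of the 20 simple epithelial and junction genes that hold these 4, 11 reached a mean of 1 RPKM and 3 were listed at 0 in both libraries, EPCAM, ESRP1 and GRHL2, while CDH1, E-cadherin, stood at 0.0163 and 0.0250 RPKM; these last 4 were named after their values were seen. Of 21 RPE visual cycle and identity genes in the table, 11 were listed at 0 in both libraries, among them RPE65, RLBP1, LRAT and TTR, and 4 reached a mean of 1 RPKM. These 4 were RDH11, at 13.2 and 11.9 RPKM, MITF, at 9.70 and 9.88, STRA6, at 7.83 and 7.98, and BEST1, at 2.14 and 1.73. Among the 10 melanin synthesis genes, 6 were listed at 0 and only MC1R reached a mean of 1 RPKM, at 1.92 and 1.60. Of the 12 endothelial, 14 leukocyte and 15 photoreceptor and neuronal genes, 1 each reached 1 RPKM, namely ENG (2.83 and 2.52), CD68 (6.17 and 5.93) and TUBB3 (1.73 and 2.31). Among 17 stratified squamous genes, SFN (84.0 and 85.0) and KRT17 (25.5 and 28.8) reached it. The 6 measured fibroblast and smooth muscle genes, led by S100A4 at 571 and 562 RPKM, had a median log2 ratio of -0.02, at percentile 73.3 of random lists. The 11 measured epithelial genes had a median of -0.03, at percentile 69.1, with F11R, a tight junction adhesion protein, at -0.25 and KRT19 at 0.13.

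The series set out to find mRNAs, long noncoding RNAs and microRNAs that differ in RPE cells with and without clusterin. CLU, the gene of clusterin itself (chromosome 8, 27596917 to 27615031, GRCh38), stood at 35.9 RPKM in the control and 33.8 in the clusterin library, a log2 ratio of -0.09. The recovered reads, 4532 and 3699, gave an RPKM ratio of 0.941 with a 95% counting interval of 0.900 to 0.983. Over 12227 genes with at least 100 reads, the median log2 ratio of reads was also -0.09. CLU thus lay at the general offset between the libraries, and an interval below 1 does not set it apart from other genes. As the treatment added protein, this level describes the cells' own transcript and does not check the labels. Among the genes furthest apart between the libraries were the histone H3 genes HIST2H3A and HIST2H3C, both lower with clusterin, and the histone H2B pseudogene HIST2H2BC, higher with clusterin.

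Most genes differed little. The median log2((clusterin RPKM + 1)/(control RPKM + 1)) over the 13244 genes was -0.06, 98.6% of genes lay within 0.5 of 0, and 70.2% lay below 0. Across genes, which are not independent replicates, Pearson's r of log2(RPKM + 1) was 0.995. At least a 2-fold difference on this scale was seen for 29 genes, 14 higher and 15 lower in the clusterin library. Small RNA genes made up 23 of the 29, with 6 to 42 reads over both libraries and a median of 11. The count was 76 with a pseudocount of 0.1 RPKM, 5 with a pseudocount of 5, and 6 among genes with at least 100 reads. On this scale the fold of low genes is understated.

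**Figure D1:**
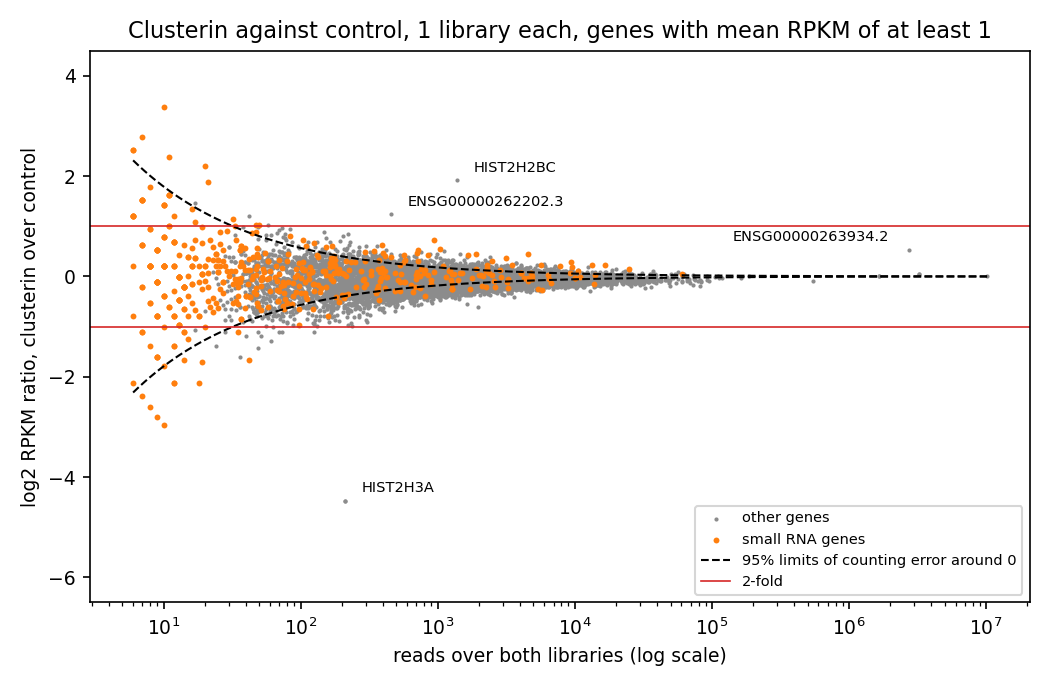
Log2 RPKM ratio of clusterin over control against the reads over both libraries (log scale), 1 point per gene reported here with a mean of at least 1 RPKM and recovered reads; dashed lines are the 95% limits of counting error around 0 and red lines mark 2-fold. Small RNA genes (orange) fan out at few reads, and HIST2H3A, HIST2H2BC and ENSG00000262202.3 lie beyond 2-fold at over 100 reads.

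HIST2H3A (chromosome 1, 149852619 to 149853125) and HIST2H3C (chromosome 1, 149840687 to 149841193), on GRCh38, carried identical values, 10.5 RPKM in the control and 0.476 with clusterin, from 204 and 8 reads, with a ratio of 0.0452 (0.0193 to 0.0908). HIST2H2BC (chromosome 1, 149850192 to 149850773) stood at 14.5 and 54.9 RPKM, from 322 and 1060 reads, with a log2 ratio of 1.85 and an RPKM ratio of 3.79 (3.35 to 4.31). ENSG00000262202.3 also passed 2-fold and stood at 6.16 and 14.5 RPKM, a ratio of 2.36 (1.93 to 2.89); it was named after its values were seen. The levels of these histone genes are uncertain, since reads from near-identical copies cannot be told apart.

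Among the other lowest genes, none of those named here past 2-fold, were ACYP1, an acylphosphatase, from 178 and 88 reads at log2 -0.68, SPA17, a sperm surface protein, at -0.63, MED30, a subunit of the Mediator complex, at -0.62, VAMP5, a SNARE protein, at -0.61, and AMH, anti-Müllerian hormone, at -0.59. The RPKM ratio of AMH was 0.506 (0.378 to 0.671) from 164 and 72 reads, and that of MED30 was 0.573 (0.434 to 0.751). RNA5-8S5, the 5.8S ribosomal RNA, stood at 840 and 544 RPKM, a log2 ratio of -0.62, without a counting interval because its reads were not recovered. Another ribosomal RNA, RNA45S5, went the other way, at 8.15% of control and 8.71% of clusterin reads with its length taken from RefSeq. Among the highest, EDN2, a vasoconstrictor peptide of the endothelin family, stood at 3.26 and 4.97 RPKM, with a log2 ratio of 0.49 and an RPKM ratio of 1.52 (1.23 to 1.89). The secretoglobin SCGB3A2 was at log2 0.51, from 24 and 37 reads, and the pseudogene RP9P at 0.44, from 97 and 130 reads. LOC100289361 was at 0.54, LOC646626 at 0.46 and SPG20OS at 0.45, each from fewer than 100 reads per library. The microRNA genes MIRLET7A1 and MIRLET7A3 stood at 0.80 and 0.62 from 2 control reads each, and their counting intervals of 0.472 to 30.3 and 0.330 to 25.5 included a ratio of 1.

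**Figure D2:**
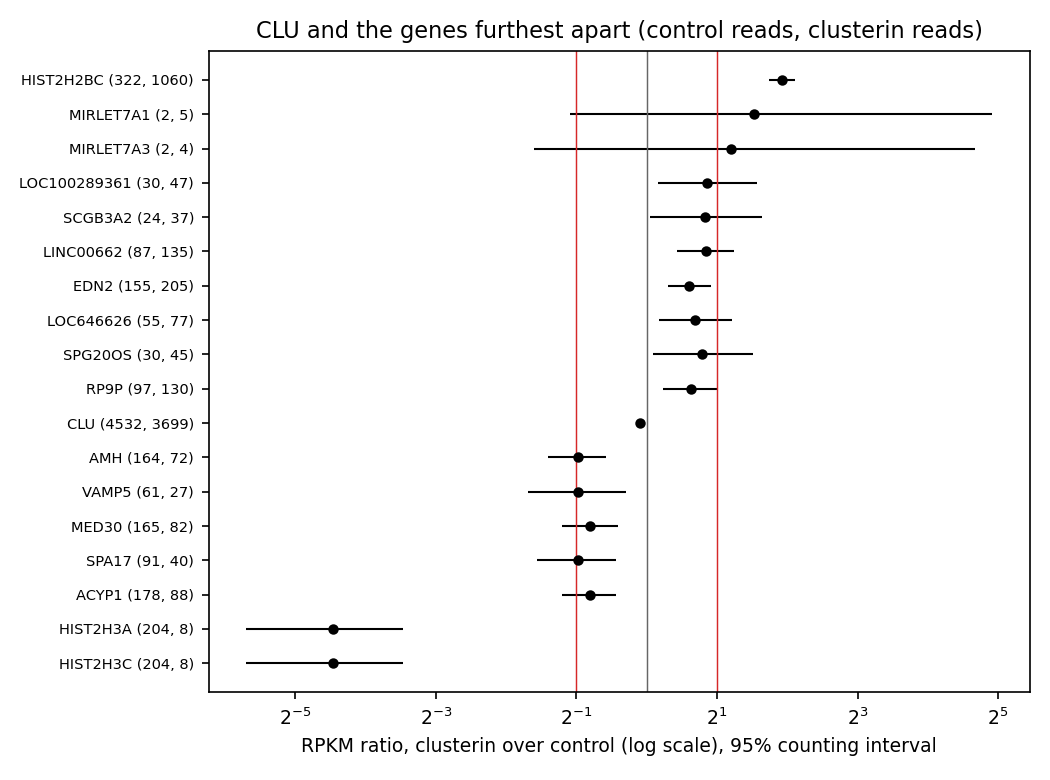
RPKM ratio of clusterin over control (log scale) for CLU and the genes named here with the highest and lowest ratios, with 95% counting intervals as bars and the control and clusterin reads in brackets; RNA5-8S5 is left out because its reads were not recovered. HIST2H3A lies far below 0.5, HIST2H2BC lies above 2, and CLU lies at 0.941.

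Of 31 gene lists with at least 5 measured members, 4 had medians outside the central 95% of 10000 random lists matched on mean expression, against 1.55 expected by chance. Cytosolic ribosomal protein genes were lower in the clusterin library: 64 of the 71 measured lay below 0, as most genes did, and 47 below the median of all genes. None passed 2-fold, and their median of -0.09 lay at percentile 0.025, with random lists spanning -0.07 to -0.02. The random lists could hold any of 497 small RNA genes, whose median was 0.03, and lists without these were not drawn. Over genes with more than 10000 reads, the median log2 ratio of reads was -0.07, so much of the -0.09 lies in the general offset. RPL23 stood at 482 and 410 RPKM (log2 -0.23), RPL27A at -0.22, RPL23A at -0.22 and RPL22 at -0.20. Many ribosomal protein genes have processed pseudogenes, so their levels carry the same uncertainty about shared reads. Cell cycle and mitosis genes were also lower, with 28 of 30 below 0 and 22 below the median of all genes, none past 2-fold, and a median of -0.10 at percentile 1. Among them the mitotic genes HMMR (5.11 and 4.05 RPKM, log2 -0.28), TTK (-0.22), PTTG1 (-0.20) and KIF20A (-0.19) were the lowest. Nuclear-encoded oxidative phosphorylation genes had 38 of 49 members below 0 and 31 below the median of all genes, none past 2-fold, and a median of -0.08 at percentile 2.3. COX5A, a cytochrome c oxidase subunit, stood at 90.2 and 75.8 RPKM (log2 -0.25), SDHC, of succinate dehydrogenase, at -0.25, and the complex I genes NDUFB5 and NDUFA4 at -0.24 and -0.21. Immediate early genes stood apart on the high side, with 12 of 18 above 0 and 14 above the median of all genes, none past 2-fold, and a median of 0.03 at percentile 99.5. The MAP kinase phosphatase DUSP6 was at log2 0.18, SPRY2 at 0.17, JUN at 0.13 and FOSL1 at 0.13, and the counting interval of each RPKM ratio included 1, while ATF3, also on that list, was at -0.52. These 4 medians kept their signs when the control was rescaled to a median of 0 and after quantile normalization. With list means, the immediate early genes (percentile 95.2) and cell cycle genes (3.09) no longer stood apart, and against unmatched random lists the ribosomal protein (3.08), cell cycle (3.45) and oxidative phosphorylation genes (16.2) did not either. The immediate early genes were at percentile 96.2 with a mean of at least 5 RPKM, and the oxidative phosphorylation genes at 3.01 with a pseudocount of 5 and at 6.79 after quantile normalization.

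**Figure D3:**
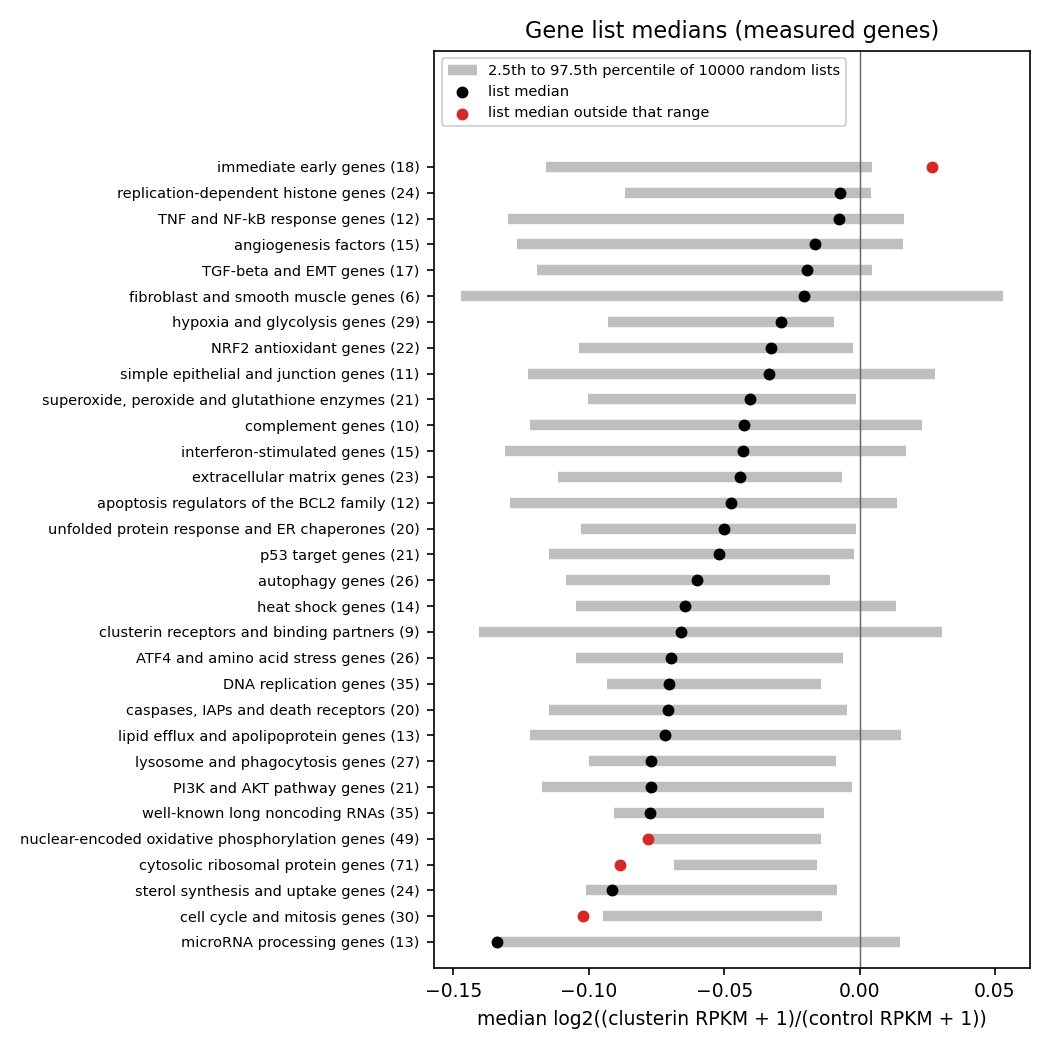
Median log2((clusterin RPKM + 1)/(control RPKM + 1)) of each gene list with at least 5 measured members (number in brackets), against the central 95% of 10000 random lists matched on mean expression (grey bars). The 4 lists outside their range (red) have medians between -0.10 and 0.03.

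Stress and death pathways did not stand apart. Clusterin receptors and binding partners had a median of -0.07 at percentile 42.3, with the apoptosis effector BAX at -0.18. The BCL2 family had a median of -0.05 (percentile 64.5), with the proapoptotic genes BMF at -0.28 and BBC3 at 0.23, and caspases, IAPs and death receptors had -0.07 (percentile 37.2), with APAF1 at -0.19 and TNFRSF10A at 0.17. NRF2 antioxidant genes had a median of -0.03 (percentile 80.3), but members differed: HMOX1, heme oxygenase, stood at 4.69 and 3.28 RPKM (ratio 0.6996, 0.576 to 0.848) and AKR1C3, an aldo-keto reductase, at 5.96 and 7.84 (ratio 1.32, 1.16 to 1.497). Superoxide, peroxide and glutathione enzymes had -0.04 (percentile 67.6), with MGST2 at -0.27 and GSS at -0.21. ATF4 and amino acid stress genes had -0.07 (percentile 28.7). Their most distant members were the stress transcription factors ATF3, at 1.58 and 0.805 RPKM (ratio 0.509, 0.377 to 0.681), and DDIT3, at 7.33 and 5.42 (ratio 0.740, 0.620 to 0.882). Unfolded protein response genes had -0.05 (percentile 54.5), with SDF2L1 at 0.26 and PDIA4 at -0.18, heat shock genes -0.06 (percentile 30.8), with HSPE1 at -0.21 and BAG3 at -0.15, and p53 targets -0.05 (percentile 59.4), with SESN1 at -0.28.

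Inflammatory and matrix lists also lay within their random ranges. TNF and NF-kB response genes had a median of -0.01 (percentile 91.1), with NFKBIE at -0.23 and TNFAIP3 at -0.14, interferon-stimulated genes -0.04 (percentile 68.1), with IFIT1 at -0.17 and ISG20 at -0.15, and complement genes -0.04 (percentile 61.7), with CFD at 0.15 and C3 at -0.14. Extracellular matrix genes had -0.04 (percentile 72.8), with COL4A5 at -0.14 and TIMP3 at 0.14, TGF-beta and EMT genes -0.02 (percentile 88.8), with PMEPA1 at -0.21 and SNAI2 at -0.18, and angiogenesis factors -0.02 (percentile 86.9), with ANGPTL4 at 10.3 and 12.8 RPKM (log2 0.30) and PDGFA at 0.17. Hypoxia and glycolysis genes had -0.03 (percentile 85.5), with CA9 at 0.17 and EGLN3 at 0.16.

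Sterol synthesis and uptake genes had a median of -0.09 at percentile 6.11, with 21 of 24 below 0 and 17 below the median of all genes. STARD4, a cholesterol transfer protein, stood at 4.91 and 3.55 RPKM (ratio 0.724, 0.619 to 0.846) and HSD17B7 at 7.51 and 5.85. By list means the sterol genes stood apart, at percentile 1.11. Lipid efflux and apolipoprotein genes had -0.07 (percentile 32.4), with SCD, stearoyl-CoA desaturase, at 98.5 and 85.6 RPKM and LPCAT3 at log2 -0.17. Lysosome and phagocytosis genes had -0.08 (percentile 17.8), with GLB1 at -0.26 and PROS1 at -0.18, autophagy genes -0.06 (percentile 52.2), with WIPI1 at -0.35 and GABARAP at -0.24, and PI3K and AKT pathway genes -0.08 (percentile 29.4), with GSK3A at -0.32 and PIK3CA at -0.21. DNA replication genes had -0.07 (percentile 21.6), with POLE2 at -0.34 and RFC2 at -0.18. Replication-dependent histone genes had -0.01 (percentile 93.8), with HIST2H2AA3 at -0.38, from 30 and 16 reads, and HIST2H2BE at 0.25. MicroRNA processing genes had the lowest median, -0.13, at percentile 2.66, with AGO4 at -0.25 and AGO1 at -0.20. That list stood apart against unmatched random lists, at percentile 1.9, and with the control rescaled, at 2.17. No mitochondrially encoded gene was listed in the table.

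None of 195 long noncoding genes passed 2-fold, in a group chosen by symbol. Their median log2 ratio was -0.06, equal to that of all genes at this rounding. LINC00662 was the highest, at 1.11 and 1.98 RPKM from 87 and 135 reads (ratio 1.79, 1.36 to 2.37), followed by LINC00235 at log2 0.37, SERTAD4-AS1 at 0.35, LINC00875 at 0.29 and ADPGK-AS1 at 0.25. LINC00263 was the lowest, at 2.86 and 1.71 RPKM from 108 and 56 reads (ratio 0.598, 0.425 to 0.833), followed by LINC00313 at -0.50, MYCBP2-AS1 at -0.45, PRKAG2-AS1 at -0.44 and BACE1-AS at -0.40. The 35 measured well-known long noncoding RNAs had a median of -0.08 at percentile 10.6, with SNHG5 and JPX each at -0.25. For antisense genes the strand used in counting was not given, so reads of the gene on the opposite strand cannot be excluded.

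Of 231 microRNA genes, 7 were past 2-fold on the high side and 9 on the low side, all read from their hairpin loci in a library of long RNA, which does not measure mature microRNAs. MIR93 had 4 control and 16 clusterin reads, a ratio of 4.61 (1.49 to 18.9), MIR1281 had 1 and 9 reads (ratio 10.4, 1.44 to 455), and MIR23A had 33 and 9 (ratio 0.314, 0.132 to 0.671). These 3 were named after their values were seen, out of 231, so intervals without 1 do not by themselves set them apart from counting error. Other microRNA genes past 2-fold, MIR1204 and MIR4668 among them, had intervals that included 1.

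In the authors' deposited table, q lay below 0.05 for 2478 of 20642 genes above 0, 337 higher and 2141 lower with clusterin, so 86.4% of them were lower. These q-values compare the 2 libraries, not the conditions, because their p-values count only read sampling error. The median size of the calls with a mean of at least 1 RPKM was 1.15-fold in either direction, and 195 of all calls were at least 2-fold apart in RPKM, 55 higher and 140 lower. When the same test was rerun here on the recovered reads of 18552 genes, 348 were called higher and 2211 lower at the deposited totals, and 971 higher and 406 lower with the median log2 ratio set to 0; the second scaling moves every gene alike, so the balance follows largely from it and says little about the genes. The spread between the libraries was larger than counting error at every depth: its robust SD was 1.502 times the counting error for genes with 1000 to 3000 reads and 2.83 times above 10000 reads. In the authors' deposited table, CLU had a q of 0.0485, HMOX1 0.00396, AKR1C3 0.000671 and LINC00662 0.000628.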

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

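Tests that set the median log2 ratio to 0, left out structural RNAs, required 100 reads, kept symbols only, used 1.5-fold, widened the long noncoding group, or applied the rescaled control to lists and named genes and quantile normalization to CLU were chosen after seeing the data. The count of 29 genes past 2-fold moved to 76 with a pseudocount of 0.1 RPKM, 5 with a pseudocount of 5, 7 with a mean of at least 5 RPKM, 6 without small RNA genes, 6 with at least 100 reads over both libraries and 115 at 1.5-fold; the last follows from the lower threshold, and for the others the fewer low genes or the pseudocount's own weight on low genes changes the count. The count of genes past 2-fold was 36 without a filter on low values and 28 under either other scaling or with symbols only. The count of long noncoding genes past 2-fold stayed 0 under 8 alternatives, 1.5-fold included. It was 1 when Ensembl identifiers and RefSeq long noncoding genes were counted, which adds ENSG00000262202.3. Ensembl identifiers entered that wider group whatever their gene type, so ENSG00000262202.3 is not shown to be long noncoding. The number of lists that stood apart was 4, and 2 against unmatched random lists, of which 1 was among the 4; the cause was not tested. It lay between 3 and 5 under the 6 other alternatives. The authors' calls, 2478 in all, came to 195 with at least a 2-fold difference. The same test rerun here on the 18552 genes with recovered reads called 348 higher and 2211 lower at the deposited totals, 1377 in all with the median log2 ratio at 0 and 1435 with totals that leave out 5 abundant structural RNAs; these compare with the rerun, not with the 2478. CLU stayed lower, from -0.09 with a pseudocount of 0.1 RPKM to -0.03 with the control rescaled. Of 104 named genes, 1 changed sign, CD68, from -0.05 to 0.01 after quantile normalization and to 0.00249 with the control rescaled. No paired analysis was possible because each group has 1 library, and leaving out a replicate is not possible for the same reason. Depth limits the small RNA genes most: those past 2-fold rest on at most 42 reads.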

Other observations

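The most abundant RNAs in both libraries were not messenger RNAs, although the protocol enriched polyadenylated RNA. The gene listed as ENSG00000258486.2 took 14.2% of control reads (exact 95% interval 14.2% to 14.2%) and 14.3% of clusterin reads, RMRP, the RNA of the mitochondrial RNA processing ribonuclease, 4.47% and 4.598%, and RPPH1, the RNA of ribonuclease P, 2.30% and 2.31%. SNORD3A, the U3 small nucleolar RNA of ribosomal RNA processing (ENSG00000263934.2 in the table), took 3.21% of control reads (3.20% to 3.21%) and 4.63% of clusterin reads (4.63% to 4.64%), a log2 ratio of 0.53. Other small nucleolar RNAs with high levels were also higher in the clusterin library: SNORD94 stood at 74.1 and 123 RPKM (log2 0.72), SNORD22 at 433 and 592 (0.45), SNORD10 at 808 and 987 (0.29) and SNORD17 at 909 and 1070 (0.24). These 4 were chosen after their values were seen, and over all 255 guide RNA genes the median log2 ratio was 0.04, with 5 past 2-fold on the high side and 2 on the low side.

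Both libraries also held high levels of genes outside the RPE marker lists. The imprinted noncoding RNA H19 stood at 8859 and 8976 RPKM, ALPP, placental alkaline phosphatase, at 216 and 234, and CPS1, the mitochondrial enzyme that starts the urea cycle, at 165 and 150. CENPE, a kinetochore motor on the cell cycle list, was at 1.52 and 2.17 RPKM (ratio 1.43, 1.27 to 1.61), against the direction of that list. These genes were chosen after their values were seen.

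Of the tests that follow, those on the H3 genes and HIST2H2BC were chosen after the result was seen. HIST2H3A and HIST2H3C are among 4 pairs of genes reported here, outside the small RNA genes, that carry identical values at separate places. Of these pairs 25% passed 2-fold, against 1 of 10829 other genes listed by symbol, small RNA genes again left out. That 25% is the H3 pair itself, so the comparison is no separate support for shared reads. In the clusterin library 0 of the 9 other measured H3 genes were below HIST2H3A, and in the control 1 was, HIST1H3J. Counting error is argued against for this pair, since the upper bound of its ratio was 0.0908. Reads that fit either copy, and were kept or dropped differently in the 2 libraries, may be the source of the difference, but with 4 pairs this cannot be told apart from an effect of clusterin, which was not tested.

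For HIST2H2BC, counting error is argued against by the lower bound of its ratio, 3.35. If reads had moved to it from the related genes HIST2H2BE and HIST2H2BF, these could have been lower with clusterin, but they lay at log2 0.25 and 0.15. That does not exclude shared reads, since the gain of HIST2H2BC, 781 reads, was 5.05% of the reads of HIST2H2BE on its listed span. Shared reads and an effect of clusterin cannot be told apart here.

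The surplus of lower genes among the calls in the authors' deposited table, 86.4%, could come from a few structural RNAs that take more of the clusterin library. RNA45S5 and the 4 most abundant RNAs above, chosen after their shares were seen, took 32.3% of control and 34.6% of clusterin reads, with the length of RNA45S5 taken from RefSeq. Without them in the totals, 61.6% of the 1435 calls rerun on recovered reads were lower. A binomial 95% interval over these calls, 59.0% to 64.1%, spans the bound of 60% set before that test. That interval treats the calls as independent, which genes of the same 2 libraries are not. The rerun at the deposited totals called 2211 lower and 348 higher. Of the median log2 ratio of -0.09, -0.04 remained. The structural RNAs thus may account for part of the surplus, and whether they account for all of it cannot be told apart from other causes. Among 4 equal groups of genes by length, the lowest share of lower calls was 79.1%, in the shortest genes, and the highest was 95.4%, in the longest. These calls were made at the deposited totals, where the general offset puts every group lower. For genes with a mean of at least 5 RPKM, the median log2 ratio was -0.05 in the shortest group and -0.08 in the longest. The test therefore cannot decide whether gene length accounts for part of the surplus.

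For the 4 gene lists that stood apart, gene length was tested as a cause with random lists matched on length as well as mean expression. It is argued against for the immediate early genes, which stayed at percentile 99.3. The ribosomal protein genes stayed at 0.07 and the oxidative phosphorylation genes were at 2.15 (3.34 for the same genes matched on mean expression alone). Their median lengths were 731 and 1059 nt, against 2555 nt for all genes, and the matched lists could hold small RNA genes, which are also short. For these short genes the test cannot decide about length among messenger RNAs. The cell cycle genes were at 3.58, but were already at 3.06 when only genes with a recovered length were used, so length cannot be told apart there. An effect of clusterin and a difference between any 2 cultures stay open for all 4 lists, since the group and the library are the same thing in this design.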
